A study of Homo sapiens with 6 samples.

How the data were processed

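Each of the 6 samples, 3 treated with vehicle and 3 with dexamethasone, was represented by the scanner output of 1 Agilent array with a single Cy3 channel. The deposited values are spot intensity values on a linear scale, which Agilent Feature Extraction 9.5.3.1 wrote per the file headers (version 9.5 per the submitters' processing notes), and the headers name hg17 (NCBI35) as the annotation build. The processed signal used here had been background-subtracted and spatially detrended by that software, per the file headers. RNA was amplified linearly and labelled with Cy3, per the labels' protocols. The series value table held the processed signal of the same arrays in all 45015 spots per array within a tolerance of 1e-06, on a linear scale and without centring, with column medians from 316.4 to 448.1; it has no direction to settle.

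Control spots were left out, leaving 43376 spots and 41000 probes per array, and so were spots marked as non-uniform or population outliers (81 to 194 per array). The log2 of the processed signal was reduced by each array's 75th percentile over non-control probes, and spots of one probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which 28581 probes were. A further 12 of these were left out because too few unmarked spots remained, so 28569 were tested. The design was a model with group alone in limma 3.58.1 (R 4.3.3, statmod 1.5.0; files were read with version 1.17.8 of data.table), with lmFit, eBayes and Benjamini-Hochberg adjustment over probes, at an adjusted p below 0.05. A gene was represented by its tested probe with the highest mean signal. Of 273 called genes with several probes, 0 had probes called in opposite directions. All changes are dexamethasone minus vehicle on the log2 scale. The standard errors are those of the moderated fit.

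Where a gene was not well above background on any array of a group, its fold is a lower bound, written as at least N-fold. It sets the mean of the bright group against the mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. That lowest signal is an extreme value rather than a detection limit, so the bound is a working value and not a guaranteed minimum. Exon, intron and UTR annotation of the probes was not used here, and coordinates are those of the scanner files. Symbols were updated through a RefSeq gene table (GRCh38), used for names and gene order alone: 23434 probes matched by accession, 2317 by current symbol and 1043 by a unique older symbol, and 14206 kept the name in the file.

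The genes named, the alternatives and 30 gene lists were fixed before the data were examined. Named genes are the 12 with the largest positive and the 12 with the largest negative log2 change among genes with a symbol, past the threshold and without overlap between groups. To these were added NR3C1, FKBP5, TSC22D3, PER1, DUSP1, SGK1, IL6, CXCL8 and CCL2, and from each list up to 4 tested members with the smallest p. TIPARP, ID3, SMAD7, NOG, LPL, PFKFB3, IRS1, IL1B, MT2A, EPCAM, KRT8, KRT14, KRT19, CLDN7, the gene pairs and the steroid enzyme genes of the closing section were chosen after their values were seen. Some results for single genes are not reported here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, with an estimated correlation and fry beside it. Camera compares a list with the other genes, whereas fry tests whether a list's genes move, on balance, one way and compares them with no other genes. At the preset correlation 6 lists passed, with an estimated correlation 0 and in fry 1.

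The vehicle and dexamethasone arrays of one number shared a slide, and all arrays were scanned on 1 day. Deviations from the group means correlated by 0.737, 0.598 and 0.549 between same-numbered arrays across probes, so the numbers were taken to pair the samples, and a fit with the number as a block is given beside the counts and named values that it changed. A two-sided exact permutation test of 3 against 3 samples cannot go below a p of 0.1, so limma's adjusted p is given. The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, a filter on all 6 arrays, the block, the value table, eBayes with trend and robust fitting, array weights, the mean of a gene's probes, stricter thresholds, leaving out each array and, added after seeing the data, leaving out slide 1 and making the dim signal equal. For the last, a constant was added to each array on the linear scale so that 8763 probes not well above background on any array had the same median. The fits that left out 1 array had no block, so in each of them 1 array lost its slide partner. Figures, tests of gene families and tests of neighbouring genes also rest on the fit without the block, which ignores the pairing. The fit was tested on simulated arrays with 28510 probes: of 100 probes changed by 1 on the log2 scale, 30 were recovered, of 100 changed by 2, 73 were, and 8 of 28310 unchanged probes were called. The simulated noise was independent between arrays, without pairing, and far fewer probes changed than the 1627 called in the data. These shares therefore check the code and do not give the power or error rate of the real comparison. Families of like symbols were tested with Fisher's exact test. Neighbouring genes were tested by 10000 shuffles of the calls among genes of like vehicle signal, in 40 bins, with the count that 1 in 40 shuffles exceeds as the upper bound. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, pandas 2.3.3).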

Results

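Transcript levels were measured in U-2 OS cells, a human osteosarcoma line, that stably express hGRdim4, a human glucocorticoid receptor altered in its dimerization domain. The glucocorticoid receptor is a hormone-activated transcription factor that can bind DNA as a dimer. After a day in charcoal-stripped serum, which is depleted of steroid hormones, the cells received 100 nM dexamethasone, a synthetic glucocorticoid, or water as vehicle for 6 h. Each group had 3 samples, and each sample was labelled with Cy3 and hybridised to 1 Agilent array. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Between 28001 and 29771 of 41000 probes were well above background per array (68.3% to 72.6%), and the 75th percentile of the signal lay between 3125 and 4354 intensity units. The number of arrays limits the precision. Same-numbered vehicle and dexamethasone arrays shared 1 of 3 slides, with every vehicle array at position 3 and every dexamethasone array at position 4.

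The comparison of dexamethasone with vehicle asks which genes respond to hormone in cells that carry this receptor. SGK1, a serum- and glucocorticoid-induced kinase, rose by 3.35 on the log2 scale (SE 0.17, n = 3 per group), and FKBP5, a co-chaperone of the receptor, by 2.31 (SE 0.14). PER1, a clock repressor, rose by 2.26 (SE 0.20) and TSC22D3, the anti-inflammatory protein GILZ, by 2.17 (SE 0.24). ATP4A, the catalytic subunit of the gastric proton pump, and KDF1, a regulator of keratinocyte differentiation, were not well above background on any vehicle array and were at least 1180-fold and at least 649-fold higher with hormone. Genes that fell included FGF5 (log2 change -2.91, SE 0.12), TGFB2 (-2.25, SE 0.28), LIF (-2.01, SE 0.19), EDN1, the endothelin-1 precursor (-1.98, SE 0.13), and IL11 (-1.89, SE 0.18). Cell cycle, ribosomal and housekeeping lists had no member past the threshold.

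In all, 1304 of 21301 tested genes passed an adjusted p of 0.05 in limma, 924 higher and 380 lower with dexamethasone. With genes dim in one group at their bound, 746 of the higher and 166 of the lower genes changed at least 2-fold. Among genes with a current reference symbol, 676 were higher and 278 lower. With the slide as a block, 3722 genes passed, 1975 higher and 1747 lower, and all 1304 genes were among them. Higher genes made up 53.1% of calls with the block against 70.9% without it. Within slides 1, 2 and 3 the called genes had a median absolute log2 change of 1.47, 1.64 and 1.38. They had the direction of the fit in 1304 of 1304, 1302 of 1302 and 1303 of 1303 cases, which is not independent of the call, since it was made on the same arrays. The vehicle and dexamethasone values did not overlap for 4652 genes, 21.8% against the 10% that chance gives for 3 against 3 independent arrays. Same-numbered arrays were paired, however, and the 3 other splits that part all 3 pairs gave 1.1% to 2.7% and the remaining 6 splits 5.3% to 18.9%. Leaving out a single array moved the count most without vehicle replicate 2 (741 genes), vehicle replicate 3 (769) or dexamethasone replicate 2 (778).

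**Figure D1:**
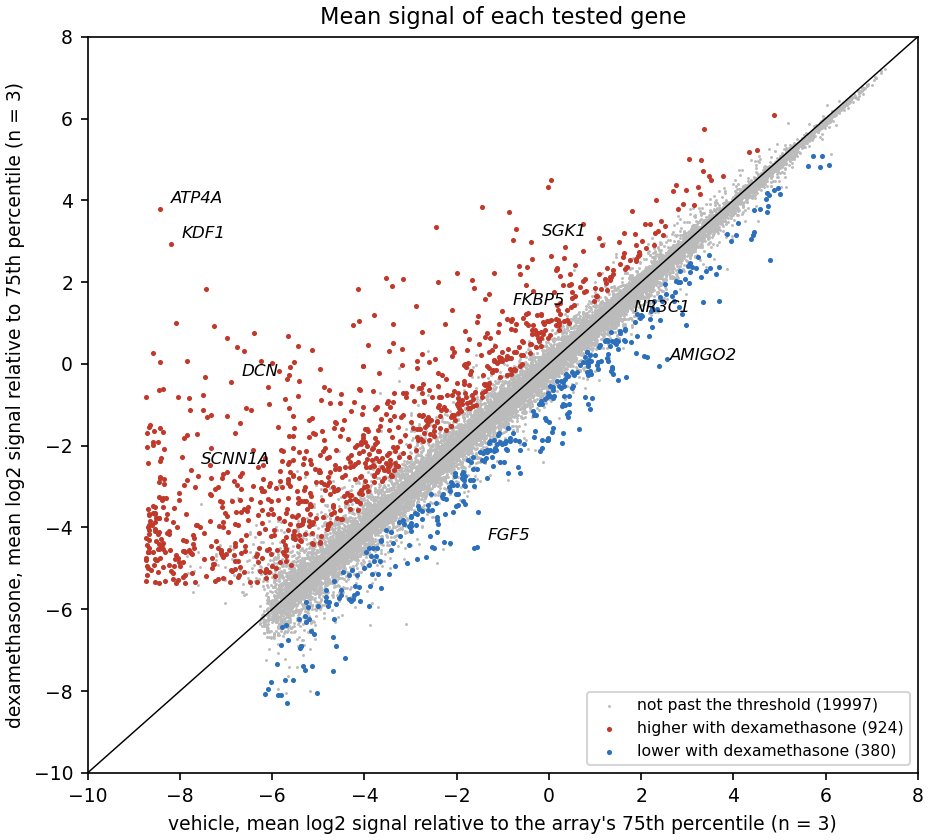
Each point is a gene, with its mean log2 signal relative to the array's 75th percentile in vehicle (x axis, n = 3) and dexamethasone (y axis, n = 3). Red points are the 924 genes higher with dexamethasone and blue points the 380 lower, the black line marks equal signal, and many red points lie at the left edge, where vehicle signal is at background.

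Among the genes called without the block, rises were larger than falls. The median log2 change was 1.97 among the 924 higher and -0.99 among the 380 lower genes, or 1.75 and -0.95 with dim genes at their bound. The higher genes were dimmer in vehicle (median log2 signal -4.36, against -0.84 for the lower genes), so these sizes are not compared at like signal. Sizes among the genes called with the block are not given here. Of the higher genes, 211 (22.8%) were not well above background on any vehicle array, and of the lower genes 26 (6.8%) were not well above background on any dexamethasone array. The filter shapes these shares, since a gene dim in one group was tested only if it was well above background on all arrays of the other, which left 224 tested genes dim in vehicle and 150 dim with dexamethasone. Among genes well above background on at least 1 array of each group, 713 were higher and 354 lower. Beside this, the 10059 probes that were not well above background on any vehicle array had a median log2 change of 0.37, with a lower quartile of 0.21 and an upper quartile of 0.52.

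The 12 named genes with the largest rises were chosen by size of fitted change. Besides ATP4A (adjusted p = 4.88e-05) and KDF1 (adjusted p = 1.18e-05), they comprised SYT13, a synaptotagmin (at least 306-fold), SPINK13, a Kazal-type protease inhibitor (at least 172-fold), TMEM204 (at least 132-fold) and RFPL3 (at least 103-fold). They also comprised SCGB2A1, a secretoglobin (at least 89-fold), NLRP7, an NLR family member (at least 88-fold), CNGA3, a cyclic nucleotide-gated channel subunit (at least 55.8-fold), PLPPR4 (at least 49-fold) and ZNF366 (at least 29.2-fold). None of these 11 was well above background on any vehicle array. CHST15, a chondroitin sulfotransferase, rose with a fitted change of 8.19 (SE 0.76), a size that is uncertain because only 1 of 3 vehicle arrays was well above background. The ATP4A probe lies on chromosome 19 at 40732940 to 40732999 and the KDF1 probe on chromosome 1 at 26960264 to 26960323, in the hg17 build of the scanner files. RFPL3 belongs to a family of similar genes, and its assignment to one of them is uncertain.

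Among the 12 largest falls, FGF5 (a fibroblast growth factor), FRMD5 (-2.45, SE 0.20), AMIGO2, an adhesion protein of the leucine-rich repeat family (-2.44, SE 0.14), TGFB2, and CLDN1, a tight junction claudin (-2.23, SE 0.21), were well above background on all 6 arrays. So were NAV3 (-2.22, SE 0.26), IER3 (-2.16, SE 0.44) and CCL3L3, a chemokine (-2.09, SE 0.29). CCL3L3 is a multi-copy gene closely related to CCL3, so its assignment is uncertain. RUNX1T1, a transcriptional corepressor, DRD1, the D1 dopamine receptor, TAS2R39, a bitter taste receptor, and HS3ST3A1, a heparan sulfate sulfotransferase, were not well above background on any dexamethasone array. They were at least 2.53-fold, 1.98-fold, 1.38-fold and 1.1-fold lower, in that order. The FGF5 probe lies on chromosome 4 at 81564985 to 81565044 (hg17). Without single arrays the calls of DRD1 (highest adjusted p = 0.141, without vehicle replicate 3), IER3 (0.145, without vehicle replicate 3) and TAS2R39 (0.0734, without dexamethasone replicate 2) were lost. Those fits had no block. With all 6 arrays and the block, limma's adjusted p was 0.00617 for DRD1, 0.000543 for IER3 and 0.0106 for TAS2R39. All 1304 called genes passed with the block, so it does not tell stable calls from unstable ones. On slides 1, 2 and 3, IER3 changed by -2.17, -2.19 and -2.12.

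Among 34 tested genes known to be induced through glucocorticoid response elements, 16 rose, 1 fell and 17 did not pass (20 rose and 1 fell adjusted over the list alone, 19 rose and 1 fell with the block). The rises included SGK1, FKBP5, RGS2, a regulator of G protein signalling (2.13, SE 0.15), TIPARP, a mono-ADP-ribosyltransferase (1.69, SE 0.14), and SCNN1A, the alpha subunit of the epithelial sodium channel (at least 14.1-fold, not well above background on any vehicle array). EDN1 was the member that fell. DUSP1, a phosphatase of the MAP kinases and a common glucocorticoid target, changed by 0.31 (SE 0.12, adjusted p = 0.291). The median change of the list was 1.04 (1.23, 1.07 and 0.93 on slides 1, 2 and 3), and camera placed the list above other genes (adjusted p = 9.82e-14). With an estimated correlation its adjusted p was 0.853 (unadjusted p = 0.0311), and fry gave an adjusted p of 0.0341.

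Of 21 tested genes commonly repressed by glucocorticoids, 4 fell, 1 rose and 16 did not pass (6 fell and 3 rose adjusted over the list alone, and 10 fell and 4 rose with the slide as a block). The genes that fell were LIF, IL11, PLAU, the urokinase plasminogen activator (-1.96, SE 0.27), and CCL2, a monocyte chemoattractant (-1.82, SE 0.31, adjusted p = 0.0212). IL1B, which encodes interleukin-1 beta, rose by 1.37 (SE 0.27, adjusted p = 0.035). Its mean log2 signal in vehicle (-6.02) was well above background on all 3 arrays but near the lowest such signals (-6.88 to -6.1). IL6 changed by 0.85 (SE 0.22, adjusted p = 0.0913, and 0.0407 with the block), and CXCL8 by -0.75 (SE 0.78, adjusted p = 0.842, and 0.0166 with the block). On the 3 slides, IL6 changed by 1.34, 0.61 and 0.60 and CXCL8 by -0.93, -0.81 and -0.50. The value of CXCL8 ranged from -0.02 without dexamethasone replicate 1 to -1.38 without vehicle replicate 1, and IL6 passed with array weights (0.62, adjusted p = 0.0349). The list as a whole did not pass in camera (median -0.25, or -0.08 with a dim member at its bound, adjusted p = 0.285). Its median was -0.015 without dexamethasone replicate 1 (camera adjusted p = 0.257) and lay between -0.3 and -0.213 without any other single array. The CCL2 call was lost in 4 of the 6 fits without 1 array (highest adjusted p = 0.0887, without dexamethasone replicate 2) and the IL1B call in 5 (0.121, without vehicle replicate 2). Both calls were kept with all 6 arrays and the block (adjusted p = 0.00386 and 0.0041), as were all 1304 calls.

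**Figure D2:**
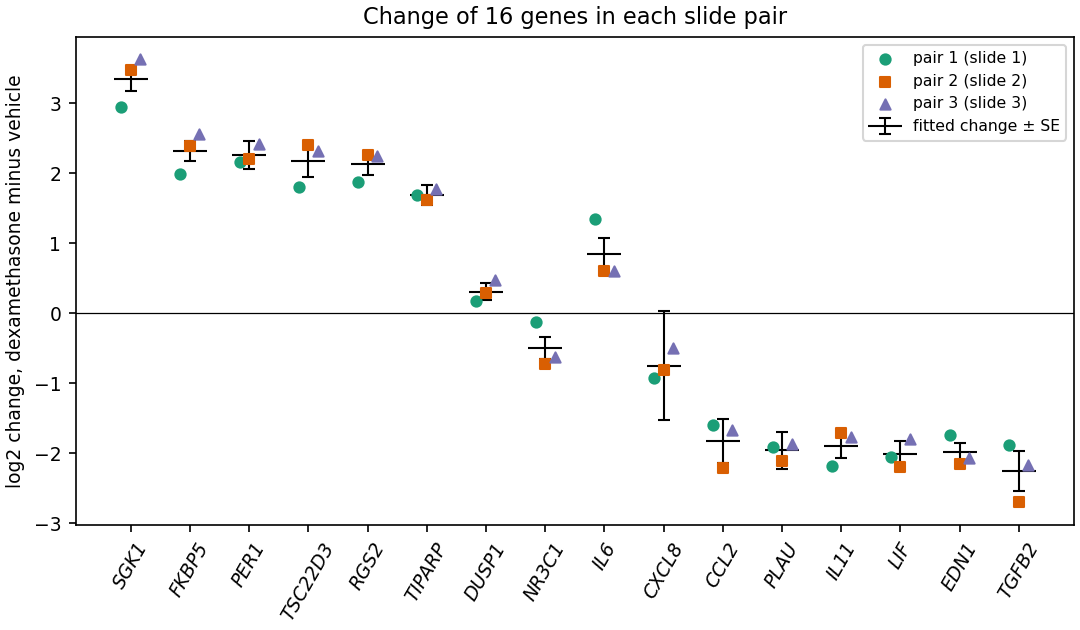
The y axis gives the log2 change from vehicle to dexamethasone of 16 genes: coloured symbols are the difference between the arrays of 1 slide (slides 1 to 3), and black bars the fitted change with its standard error (n = 3 per group). SGK1, FKBP5, PER1, TSC22D3, RGS2 and TIPARP lie above 0 on each slide, CCL2, PLAU, IL11, LIF, EDN1 and TGFB2 below 0, and the 3 symbols of IL6 are 1.34, 0.61 and 0.60.

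The receptor transcript itself, NR3C1, changed by -0.49 (SE 0.16, adjusted p = 0.164) at a probe on chromosome 5 at 142641130 to 142641189 (hg17), and by -0.55 (SE 0.12, adjusted p = 0.0559, and 0.0166 with the block) at a probe at 142639483 to 142639542. On slides 1, 2 and 3 the brighter probe gave -0.13, -0.72 and -0.62. At this probe NR3C1 gave -0.61 with array weights (adjusted p = 0.0096) and -0.67 without slide 1, a setting chosen after seeing the data (adjusted p = 0.0393); it did not pass in the other settings. It is not known here whether these probes detect the introduced receptor. Of 22 tested genes for the receptor, its chaperones and cofactors, FKBP5 rose, DNAJB1, an HSP40 co-chaperone, fell (-0.72, SE 0.12, adjusted p = 0.018), and 20 did not pass. Adjusted over the list alone or with the block, 1 rose and 2 fell, and camera gave an adjusted p of 0.22 (0.0158, lower, without dexamethasone replicate 1). The mineralocorticoid receptor gene NR3C2 changed by -1.09 (SE 0.25, adjusted p = 0.0604, and 0.0119 with the block). The DNAJB1 call was lost in 5 of the 6 fits without 1 array (highest adjusted p = 0.100, without vehicle replicate 2).

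Among 18 tested genes of NF-kB and its feedback inhibitors, BCL3, an IkB family member (-1.44, SE 0.16), and NFKBIE, the inhibitor IkB epsilon (-0.87, SE 0.14), fell, BIRC3, an inhibitor of apoptosis, rose (1.87, SE 0.33), and 15 did not pass. Adjusted over the list alone, 6 fell and 2 rose, and with the block 7 fell and 2 rose. The list did not pass in camera (median -0.27, adjusted p = 0.251, and 0.0499 without dexamethasone replicate 1). Of 20 tested AP-1 and immediate early genes, IER3, IER2 (-1.05, SE 0.22) and NR4A3, an orphan nuclear receptor (-0.76, SE 0.14), fell and MAFF, a small MAF protein, rose (1.05, SE 0.20), while 16 did not pass. Adjusted over the list alone, 7 fell and 1 rose, and with the block 9 fell and 2 rose. The median of the AP-1 list was -0.56 (-0.47, -0.51 and -0.34 on the 3 slides), 5 of 20 members had a positive change, and camera gave an adjusted p of 0.00487, against an adjusted p of 0.853 with an estimated correlation and 0.109 in fry. Without single arrays the calls of NFKBIE (highest adjusted p = 0.0775, without dexamethasone replicate 3), BIRC3 (0.091, without vehicle replicate 3), NR4A3 (0.142, without vehicle replicate 3) and IER3 (0.145, without vehicle replicate 3) were lost. So were those of MAFF (0.122, without vehicle replicate 2) and IER2 (0.171, without vehicle replicate 2). With all 6 arrays and the block, each of these genes kept its call (highest adjusted p = 0.0182, for MAFF), as did all 1304 called genes.

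Among feedback regulators of the MAP kinase pathway, DUSP5, a nuclear ERK phosphatase (-1.06, SE 0.20), and DUSP8 (-0.67, SE 0.14) fell and 15 of 17 tested members did not pass (6 fell and 1 rose adjusted over the list alone, 7 fell with the block). The list median was -0.43 (-0.25, -0.44 and -0.43 on the 3 slides), with a camera adjusted p of 0.0163, against an adjusted p of 0.853 with an estimated correlation and 0.187 in fry. The list call was lost without vehicle replicate 2 (adjusted p = 0.056) or dexamethasone replicate 1 (0.0632). The DUSP5 call was lost in 4 of 6 such fits (highest adjusted p = 0.127, without vehicle replicate 3) and the DUSP8 call in all 6 (highest 0.197, without vehicle replicate 3).

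TGF-beta and BMP pathway genes fell more often than they rose. Of 23 tested, 6 fell, 1 rose and 16 did not pass, and adjusted over the list alone or with the block 10 fell and 4 rose. The genes that fell included TGFB2, a TGF-beta ligand, TGFBI, a TGF-beta-induced matrix protein (-1.28, SE 0.15), and INHBA, the activin A subunit (-1.02, SE 0.14). Falls were also measured for CCN1, a matricellular protein (-0.85, SE 0.11), ID3, a BMP-induced inhibitor of differentiation (-0.83, SE 0.14), and SMAD7, an inhibitory SMAD (-0.76, SE 0.11). NOG, which encodes the BMP antagonist noggin, rose by 1.02 (SE 0.15). The list median was -0.38 (-0.54, -0.46 and -0.40 on the 3 slides), with a camera adjusted p of 0.00915, an adjusted p of 0.853 with an estimated correlation and 0.0717 in fry. The list call was lost without slide 1, a setting added after seeing the data (adjusted p = 0.0597), and without vehicle replicate 2 the calls of INHBA (adjusted p = 0.0518), NOG (0.0575), SMAD7 (0.0679) and ID3 (0.108) were lost. Of the 6 fits without 1 array, the INHBA call was lost in 1, the NOG call in 2, the SMAD7 call in 3 and the ID3 call in 5.

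Of 24 tested extracellular matrix genes, 4 rose. DCN, the proteoglycan decorin, was at least 62.5-fold higher and not well above background on any vehicle array. THBS2, thrombospondin 2, rose by 5.18 (SE 0.36), LOX, a collagen cross-linking oxidase, by 2.94 (SE 0.19) and COL6A1, a collagen VI chain, by 1.98 (SE 0.24). The other 20 did not pass (5 rose and 1 fell adjusted over the list alone, 7 rose and 1 fell with the block). The list median was 0.15 and its mean 0.77, with a camera adjusted p of 0.00713, an adjusted p of 0.853 with an estimated correlation and 0.109 in fry. Without single arrays the median ranged from 0.039 (without vehicle replicate 1) to 0.309 (without dexamethasone replicate 1). The list passed in camera at the preset correlation in each of these fits (highest adjusted p = 0.0416, without vehicle replicate 1). Beside this, the fibroblast markers PDGFRB (1.76, SE 0.41) and FAP (1.56, SE 0.60) and the endothelial marker VWF (1.11, SE 0.37) did not pass, and did with the block (adjusted p = 0.00503, 0.0044 and 0.0241). Of 25 tested adhesion and cytoskeleton genes, ITGA1, an integrin subunit for collagen (3.0, SE 0.13), VCL, vinculin (1.01, SE 0.13), and ITGA6 (0.86, SE 0.13) rose. CNN1, a calponin, fell (-0.67, SE 0.13) and 21 did not pass (4 rose and 1 fell adjusted over the list alone, 5 rose and 5 fell with the block). The adhesion list had a median of -0.15 and a mean of 0.03, pointed down in camera (adjusted p = 0.959) and up in fry (adjusted p = 0.0589). The ITGA6 call was lost without 3 of the 6 arrays in turn (highest adjusted p = 0.0698, without vehicle replicate 2) and the CNN1 call in each of the 6 fits (highest 0.143, without vehicle replicate 3).

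Metabolic genes moved both ways. CPT1A, the carnitine palmitoyltransferase of fatty acid oxidation, was at least 13.5-fold higher and not well above background on any vehicle array, and PDK4, a pyruvate dehydrogenase kinase, rose by 4.41 (SE 0.62). ACSL1 (1.0, SE 0.17), LPL, lipoprotein lipase (1.18, SE 0.24), and PFKFB3 (0.82, SE 0.17) also rose. SLC2A1, the glucose transporter GLUT1 (-0.83, SE 0.15), and IRS1, an insulin receptor substrate (-0.55, SE 0.11), fell. The other 18 of 25 tested members did not pass (6 rose and 2 fell adjusted over the list alone, 6 rose and 4 fell with the block, camera adjusted p = 0.6). The calls of ACSL1 (highest adjusted p = 0.0995), SLC2A1 (0.111) and IRS1 (0.17) were lost without vehicle replicate 3 and in other fits without 1 array, and so were those of PFKFB3 (0.179, without vehicle replicate 2) and LPL (0.142, without dexamethasone replicate 2). Of 13 tested genes of ion and water transport, 4 rose, among them SCNN1A, AQP3, an aquaglyceroporin (1.89, SE 0.29), and SLC19A2, a thiamine transporter (0.78, SE 0.16), and 9 did not pass (4 rose adjusted over the list alone, 4 rose and 2 fell with the block, camera adjusted p = 0.258). The calls of AQP3 (highest adjusted p = 0.0563, without vehicle replicate 3) and SLC19A2 (0.151, without vehicle replicate 2) were lost without single arrays. Of 20 tested genes of cholesterol synthesis, IDI1 (1.27, SE 0.23) and NSDHL (0.67, SE 0.14) rose and 18 did not pass (2 rose adjusted over the list alone). The list median was -0.24 and 3 of 20 members had a positive change; its camera adjusted p was 0.284, and 0.0174 with the block, where 6 members fell and 2 rose. The list also passed without vehicle replicate 1 (median -0.409, adjusted p = 0.036) or dexamethasone replicate 3 (median -0.438, adjusted p = 0.0196). Its median was -0.131 without vehicle replicate 3 and -0.12 without dexamethasone replicate 1. The IDI1 call was lost in 4 fits without 1 array (highest adjusted p = 0.104, without dexamethasone replicate 2) and the NSDHL call in all 6 (highest 0.144, without vehicle replicate 2).

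None of 10 tested metallothioneins, small metal-binding proteins of near-identical sequence that the probes cannot be assumed to tell apart, passed on its own or adjusted over the list alone, and with the block MT1M did (adjusted p = 0.0215). Their median change was 0.44 (0.20, 0.75 and 0.39 on the 3 slides) and 9 of 10 had a positive change, with MT2A at 0.15 (SE 0.14) and MT1M at 0.72 (SE 0.23). Without single arrays the median ranged from 0.274 (without dexamethasone replicate 2) to 0.56 (without dexamethasone replicate 1). Camera gave an adjusted p of 0.0026, against an adjusted p of 0.853 with an estimated correlation and 0.21 in fry. The correlation estimated between the members, without the block, was 0.78 against the preset 0.01. The members are therefore not taken as separate evidence. Of 16 tested clock genes, PER1 and NFIL3, a bZIP repressor (0.72, SE 0.15), rose and 14 did not pass (3 rose and 1 fell adjusted over the list alone, 6 rose and 3 fell with the block, camera adjusted p = 0.513). The NFIL3 call was lost in 5 of 6 fits without 1 array (highest adjusted p = 0.184, without vehicle replicate 2).

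Of 13 tested osteoblast genes, PTH1R, the parathyroid hormone receptor, was at least 2.75-fold higher and not well above background on any vehicle array. BMP2, a bone morphogenetic protein, rose by 1.21 (SE 0.16) and PHEX by 0.87 (SE 0.13). BMP4 fell (-0.77, SE 0.17), just under the threshold, and 9 did not pass (3 rose and 2 fell adjusted over the list alone or with the block, camera adjusted p = 0.63). The calls of BMP4 (highest adjusted p = 0.195) and PHEX (0.0688) were lost without vehicle replicate 3 and in other fits without 1 array. Of 17 tested WNT pathway genes, NKD1, a negative regulator of the pathway, rose by 3.36 (SE 0.24) and 16 did not pass (2 rose and 1 fell adjusted over the list alone, 2 rose and 4 fell with the block, camera adjusted p = 0.638).

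Stress and interferon lists had few members past the threshold. Of 20 tested ATF4 targets, CHAC1 (1.22, SE 0.18) and CEBPB (0.84, SE 0.15) rose and 18 did not pass (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.337). Of 20 genes of the unfolded protein and heat shock responses, DNAJB9 rose (0.70, SE 0.14), DNAJB1 fell and 18 did not pass (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.763). NDRG1 (1.27, SE 0.14) and ADM, adrenomedullin (1.11, SE 0.22), rose among 19 hypoxia genes, SLC2A1 fell and 16 did not pass (2 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.63). Among 19 tested interferon-induced genes, IFIT3 (1.21, SE 0.17) and IFI44L (2.63, SE 0.41, well above background on 2 of 3 vehicle arrays) rose. IFI44 fell (-0.62, SE 0.12) and 16 did not pass (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.258). With the block, the counts of these lists were 3 rose and 3 fell for ATF4 targets, 1 and 3 for the unfolded protein and heat shock list, 3 and 5 for hypoxia and 3 and 2 for interferon. Of the genes named here, NDRG1 kept its call in every fit without 1 array; the highest adjusted p of the others was 0.158, for IFI44 without vehicle replicate 2.

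Lists for proliferation and cell death showed few changes. No gene passed among 24 of the G1/S transition (median 0.01, camera adjusted p = 0.63), 27 mitotic (median -0.06, 0.63), 22 pro-apoptotic (median -0.03, 0.737), 27 ribosomal protein (median -0.07, 0.415) and 16 housekeeping genes (median -0.06, 0.763), nor did any adjusted over the list alone in limma. The G1/S list passed in camera without vehicle replicate 1 (median 0.117, adjusted p = 0.0416) and the mitotic list without dexamethasone replicate 1 (median -0.14, adjusted p = 0.0499). With the block, 2 pro-apoptotic genes rose and 1 fell, and 1 mitotic gene rose. BIRC3 was the 1 of 14 tested anti-apoptotic genes that rose, and 13 did not pass (1 adjusted over the list alone, camera adjusted p = 0.513). TP53I3, a p53-induced oxidoreductase, rose by 1.94 (SE 0.16) among 20 tested CDK inhibitors and p53 targets, of which 19 did not pass (1 rose adjusted over the list alone, 2 rose and 1 fell with the block, camera adjusted p = 0.63).

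Markers of other cell types were tested in the same way. Of 15 epithelial markers, GRHL2, an epithelial transcription factor, was at least 11.6-fold higher and not well above background on any vehicle array, and KRT5, a basal keratin, rose by 5.35 (SE 0.36). CDH1, E-cadherin, fell (-1.70, SE 0.23) and was well above background on 1 of 3 dexamethasone arrays, while 12 did not pass (2 rose and 2 fell adjusted over the list alone, 5 rose and 3 fell with the block). The epithelial list had a median of -0.08 and a mean of 0.59, and camera gave an adjusted p of 0.429. Of 10 haematopoietic markers, HBA1, an alpha globin nearly identical to HBA2 and therefore of uncertain assignment (2.20, SE 0.24), and CD3D (1.22, SE 0.20) rose and 8 did not pass (2 rose adjusted over the list alone, median -0.05, camera adjusted p = 0.56). The CD3D call was lost in 4 of 6 fits without 1 array (highest adjusted p = 0.0672, without vehicle replicate 2). Among 12 endothelial and fibroblast markers DCN rose and 11 did not pass (2 rose adjusted over the list alone, 4 rose with the block, median 0.20, camera adjusted p = 0.129). That list passed in camera under median scaling (adjusted p = 0.0372), without vehicle replicate 2 (0.0383), without dexamethasone replicate 1 (0.0499) and without the filter on dim probes (0.00952). Its median was -0.109 without vehicle replicate 1 (camera adjusted p = 0.437) and 0.097 without dexamethasone replicate 2 (0.155).

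**Figure D3:**
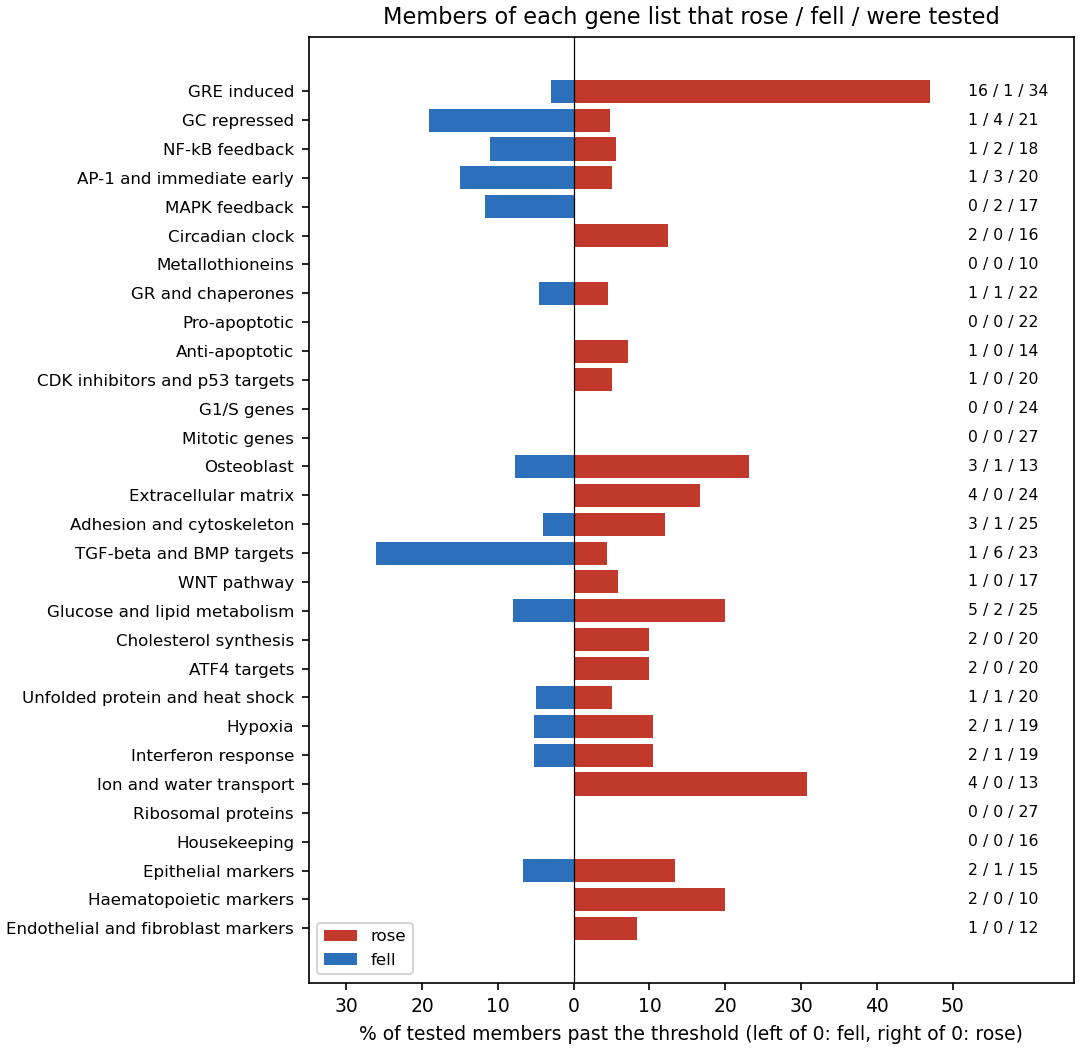
Bars show, for each of 30 gene lists, the percentage of tested members that rose (red, right of 0) or fell (blue, left of 0) with dexamethasone at an adjusted p below 0.05, with the numbers that rose, fell and were tested at the right. The list of genes induced through glucocorticoid response elements has 16 rises among 34 members and the TGF-beta and BMP list 6 falls among 23, while the proliferation, ribosomal and housekeeping lists have none.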

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

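Leaving out slide 1 and making the dim signal equal were chosen after seeing the data; the other settings were not. With the replicate block, 3722 genes passed (1975 higher, 1747 lower), and with array weights, which gave the replicate 1 arrays 0.292 and 0.295, 2540 passed (1529 higher, 1011 lower). An adjusted p below 0.01 left 645 genes (522 higher, 123 lower). Testing all probes without a filter left 208 lower genes, and testing only probes well above background on all 6 arrays left 605 higher genes, among fewer genes tested. Leaving out 1 array at a time gave 741 to 1148 genes, 585 to 877 of them higher and 144 to 291 lower, with fewer samples in each fit; without slide 1, 1349 passed (933 higher, 416 lower), 960 of them shared. The other counts of genes stayed within 1.5 times, and no gene was called in opposite directions in any setting. Median scaling put the median change of all genes at -0.122, against -0.039. The value table moved nothing, since it holds the same signal.

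Against 6 list calls in camera, 10 lists passed without the filter, which added NF-kB feedback (adjusted p = 0.0417), the receptor and its chaperones (0.0339), ATF4 targets (0.0437) and endothelial and fibroblast markers (0.00952), and 0 passed with an estimated correlation; the other settings gave counts within 1.5 times. In fry, which asks a different question of a list, 1 passed. Besides the cholesterol list, the block changed no list call in camera at the preset correlation, the only list test run with it. Of 108 genes called that were named or taken by the rule for names, 64 kept the call in all 6 fits without 1 array, and 5 lost it in each; all 108 kept it with the block, under which 32 of 63 such uncalled genes passed. BCL2A1 changed sign under the mean of a gene's probes (-0.56), since its other probe, at -1.26 (SE 0.61), enters that mean beside the one at 0.15; the cause of the other shifts was not tested. Signal over background limits the size of rises from dim vehicle probes to lower bounds.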

Other observations

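Apart from the other splits of the arrays, the tests below were chosen once the called genes were known, and those of epithelial contamination, equal dim signal and gene families after further results were seen. Genes of steroid metabolism were among the rises. HSD11B2, which inactivates cortisol, rose by 2.11 (SE 0.22), HSD3B1 by 3.07 (SE 0.48, well above background on 2 of 3 vehicle arrays), and HSD17B2 and HSD3B2 were at least 5.94-fold and 3.33-fold higher, with no vehicle array well above background. SRD5A2, a steroid 5-alpha reductase, rose by 3.81 (SE 0.29). HSD3B1 and HSD3B2 are close paralogs, so their probes are not taken as separate evidence; their calls were lost without single arrays (highest adjusted p = 0.0537 without vehicle replicate 1, and 0.093 without dexamethasone replicate 3). Among 93 families of like symbols, tested in both directions, HSD genes had 4 of 16 members higher against 0.8 expected, and this did not pass adjustment (two-sided Fisher's exact p = 0.00638, adjusted p = 0.345).

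Many of the genes called higher neighbour each other in the genome. Examples are EDN3, an endothelin, beside PHACTR3 (at least 16.5-fold higher and a log2 change of 5.77), GRHL2 beside NCALD (at least 11.6-fold and 2.83), and ARHGAP22 beside WDFY4 (3.97 and 4.04). FKBP5 lies beside ARMC12 (2.31 and at least 2.88-fold) and HAS1 beside FPR1 (at least 5.37-fold and at least 7.25-fold). On chromosome 8 the genes TG, SLA, CCN4 and NDRG1 lie in a series and each rose (log2 changes of 3.96 and 3.79, at least 3.6-fold, and a log2 change of 1.27), but TG and SLA overlap. EDN3, GRHL2, ARMC12, HAS1, FPR1 and CCN4 were not well above background on any vehicle array. The calls of ARMC12 (highest adjusted p = 0.100, without vehicle replicate 2) and CCN4 (0.137, without dexamethasone replicate 2) were lost without single arrays.

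Among 13552 protein-coding genes, 659 were called higher, and in 60 neighbouring pairs both genes were. Shuffles matched on vehicle signal gave a mean of 24.98 pairs (upper bound 34), which argues against a clustering of dim genes as the whole cause. The shuffles do not keep together tissue-restricted neighbours that are expressed together, so that explanation stays open. Without pairs of like symbols and overlapping genes, 47 pairs remained against 17.74 (upper bound 26, one-sided permutation p = 1e-04, the smallest that 10000 shuffles can give), which argues against duplicated or overlapping neighbours as the whole cause. Lower genes gave 12 such pairs against 3.36 (one-sided permutation p = 2e-04). These counts are consistent with a response to the receptor that may extend over neighbouring genes, a hypothesis that came from the called genes and was tested on the same arrays. Ordinary co-expression of neighbouring genes, receptor binding, read-through transcription and distance between genes were not tested.

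Higher genes outnumbered lower ones, 924 to 380, and 211 of them were not well above background on any vehicle array, a number that the filter favours, since genes dim in vehicle were tested only if bright with dexamethasone. A higher background on the dexamethasone arrays would raise all dim probes alike. The 10059 dim probes moved by a median of 0.37, but the slides (0.40, 0.20 and 0.51) reach past the bound of 0.5 set for the median, so this value does not decide. Spike-in controls not well above background on all arrays went both ways, at 0.305 (0.19, 0.38 and 0.34 on the slides), 0.093 and -0.146. With the dim signal made equal on all arrays, 944 genes were higher and 423 lower, which argues against an even difference in dim signal as the whole cause of the excess. The 211 genes kept their call, but this is no support. They were bright on all dexamethasone arrays and their smallest bound was 1.05 on the log2 scale, so a shift near 0.37 could hardly undo their calls. A shift that differs between probes stays open. Apart from GRHL2 and KRT5 (5.35), the 10 epithelial markers with vehicle signal below the 75th percentile changed by a median of -0.08, from -1.70 (CDH1) to 0.86 (KRT19) with EPCAM at -0.19, which argues against admixture of epithelial cells as the whole cause, but with the block KRT8 (0.48), KRT19 and CLDN7 (0.74) rose (adjusted p = 0.0261, 0.0142 and 0.0258) while CDH1, CLDN4 (-1.41) and KRT14 (-0.45) fell (0.00229, 0.00149 and 0.0234), so a small share stays open. The block narrowed the split to 1975 higher and 1747 lower, so the size of the excess depends on that setting, and a response to hormone that is larger for genes silent in vehicle stays open.

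The count of 1304 genes was set against other splits of the 6 arrays. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05; 1 split, the real one, gave as many as 1304 in limma, and the highest other gave 0, with 58 to 2648 genes at an unadjusted p below 0.05 against 3436. Among the others, the splits that part all 3 pairs gave 60, 58 and 101 such genes, and those that keep the replicate 1 arrays together 1780 to 2648. This points to a structure shared by the replicate 1 arrays. Slide 1 and other steps that these arrays may have shared cannot be told apart. Array position differed between the groups on every slide. The 7 spike-in controls well above background on all arrays changed by at most 0.06 in size as a mean over slides, with -0.17 for 1 of them on slide 1. The dimmer spike-ins changed by 0.305, 0.093 and -0.146. Called genes had a median absolute log2 change of 1.51, but they were selected for large changes, so this contrast does not test position. The spike-in values were scaled by the gene probes of the same array, so a shift common to all bright probes cancels. The bright spike-ins therefore cannot test such a shift by position. They show only that their ratio to the gene signal was nearly the same in both groups. A common shift by position stays open, as does an effect on dim or single probes. Steps before the spike-ins were added were not tested, and the order of handling in them cannot be separated from treatment.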
